A study of Mus musculus with 8 samples.

How the data were processed

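Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in AML246 cells, a mouse acute myeloid leukaemia line. The samples covered a course of doxycycline (Dox, 0.1 µg/mL) from day 0 to day 12 and the 12 days after its withdrawal. Per the labels, addition of Dox restored PU.1 and withdrawal returned the cells to PU.1 knockdown. The labels' extraction protocol also mentions ChIP; the libraries were taken as ATAC-seq because the series title, its design text and the library preparation name that assay. Each of the 8 groups held 1 library: total viable cells at day 0, 4, 8 and 12 on Dox, a CD11b-high sort at day 12, and 4, 8 and 12 days off Dox.

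Each library came as a list of peak summits, 1 base per peak, with 1 score per summit. Per the submitters' processing notes, MACS2 and Picard 2.14.0 were used and positions refer to the mouse build mm10, while the MACS2 version, the aligner and the read depth are not given in the sources used here. The deposited score was read as the −log10 of a p-value or q-value, because in the deposited lists the smallest score lay between 1.30 and 1.39, where a threshold of 0.05 falls. Which of the 2 the authors used is not given in the sources used here. The score moves with depth and was used only within a list, to rank or filter summits, except for the chromosome comparison of the closing section, where each library's scores were first divided by its own median over regions open in all 8 libraries. Peaks were called per library, so a region without a summit is a region not called, not a region shown to be closed. "Open" and "not open" are used in that sense throughout.

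Summits on chromosomes 1 to 19, X and Y were extended by 150 bp to each side and overlapping intervals were merged into regions, so that summits up to 300 bp apart fell into 1 region. Between 85 and 121 summits per library lay on other contigs and were left out. A region was open in a library when it held a summit of that library. Gained regions were not open at day 0 and open at day 4, 8 and 12. Lost regions were open at day 0 and not open at day 4, 8 or 12. Constant regions were open in all 4. With 1 library per group there was no spread between replicates, so no test between conditions was run and no p-value is given. The rules required 3 later libraries to concur, but these are different times and no replicates. Whether a region counted as gained or lost still rested on the single day-0 list. Shares carry exact Clopper-Pearson 95% intervals and odds ratios carry Woolf 95% intervals. All intervals cover counting error only, and neighbouring regions are not independent.

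The position of a library between day 0 and day 12 was expressed as the odds ratio of being open among regions open at day 0 but not day 12 against regions open at day 12 but not day 0, with its range when each chromosome was left out. Gained regions after withdrawal were set beside constant regions matched to them in 20 bins of day-12 score, and beside regions missing only at day 4 or only at day 12. Lost regions were set beside regions open only at day 4, only at day 8 or only at day 12.

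Each region was assigned to the nearest protein-coding gene within 100 kb in a RefSeq gene table of assembly GRCm38.p6, the build also called mm10. The plan used transcription start sites, but the table gives neither strand nor exons, so distance was taken to the gene's span (0 inside it) and "near a gene end" means within 1 kb of either end. Exons, introns and untranslated regions were not analysed here. The planned search for sequence motifs at summits needed a genome sequence and was not analysed here. Of 281 genes in 18 lists fixed before the data were examined, 277 matched the 21887 protein-coding genes of the table. For each list, the mean number of gained minus lost regions per gene was ranked among 10000 random gene lists of the same size matched on regions per gene. A list was said to stand apart above the 97.5th or below the 2.5th percentile, which describes these libraries and is no p-value.

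Genes to name were also fixed before the data were examined: the 12 genes with the largest and the 10 with the lowest number of gained minus lost regions, the 6 with most gained regions closed at both 8 and 12 days off, the 6 with most gained regions open at all 3 times off, the 6 with most lost regions open again at 12 days off, the 5 at each end of CD11b-high-only minus total-only regions, up to 4 members of each list, and Spi1, Itgam, Kit and Csf1r. Single regions named were the 5 gained with the highest day-12 score and the 5 lost with the highest day-0 score. Some items these rules select are not reported here.

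The rules were tested on simulated lists over the same 68800 regions. Each region's chance of a call was its share of the 8 real lists, scaled to each list's length. Any true change is therefore part of these chances, and regions open in all 8 real lists could be missed in a simulated list. The simulated counts are thus no firm measure of what unchanged cells would give. In a simulation with no change between libraries, 3405 regions passed the rule for gained and 2997 the rule for lost, and the odds ratios lay between 1.10 and 1.17. In a simulation with 3000 regions changed each way, 64.1% of the opened and 82.2% of the closed regions were recovered, and 47.2% of the regions called gained and 46.7% of those called lost were true. A simulated gene list with 1 added region per gene reached the 99.96th percentile, and 1 of 17 other lists stood apart.

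Alternatives planned before the data were examined were lists limited to the 31867 highest-scoring summits in every library, a score of at least 10, extension by 75 or 250 bp, fewer restoration libraries in the rules, and a gene distance of 20 kb. Alternatives chosen after seeing the data were leaving out chromosome 4, CD11b-high in place of total cells at day 12, not using day 8, gene lists from day 12 alone, the nearest gene end, and keeping only gained or lost regions with no summit of the other lists within 1 kb. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.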

Results

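ATAC-seq peak summits were compared in AML246 mouse acute myeloid leukaemia cells over a 24 day course in which PU.1, the ETS-family transcription factor encoded by Spi1, was restored with Dox for 12 days and then knocked down again by withdrawing the drug. Each of the 8 groups was represented by 1 library, so values describe these libraries and no replicate error could be given. The lists held 36137 summits at day 0, 35139 at day 4, 47060 at day 8 and 35201 at day 12 on Dox, 36300 in CD11b-high cells of day 12, and 51175, 41526 and 31957 at 4, 8 and 12 days off. Median scores lay between 9.40 at day 12 and 12.6 at day 4. Merging gave 68800 regions with a median length of 346 bp, of which 18733 were open in all 8 libraries and 16188 in a single library. The read depth behind the lists is not given in the sources used here, and because list length moves with it, counts of open regions are not compared directly between libraries.

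At Spi1 (chromosome 2, 91082374 to 91115759, mm10), 7 regions were assigned to the gene. Inside the gene, the region at 91082872 to 91083291, with its midpoint 707 bp from the nearer gene end, and the region at 91096507 to 91096924 were open in all 8 libraries. The region at 91081070 to 91081480, 1099 bp outside the gene, was not open at day 0, was open at day 4, 8 and 12 on Dox, in CD11b-high cells and at 4 days off, and was not open at 8 and 12 days off. Accessibility of the locus does not measure Spi1 RNA and is no check of the knockdown. At Kit, the stem cell factor receptor, the region at chromosome 5, 75574744 to 75575153, 39 bp from the gene, was open in all 8 libraries. A region inside the gene at 75615636 to 75616072 was not open at day 0 or at 12 days off. It was open at every time between, with scores of 6.11 to 11.9. Itgam, which encodes CD11b, had 6 regions, of which the region at chromosome 7, 128050689 to 128051147, 11722 bp outside the gene, was open in all 8. Csf1r, the macrophage colony-stimulating factor receptor, had 3 regions. None was open at day 0, 8 or 12, 1 was open at day 4 and another at 4 and 12 days off. In CD11b-high cells 2 were open, including the day-4 region at chromosome 18, 61105739 to 61106160. The Csf1r calls all scored low, at 2.31 to 4.49.

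The first comparison asked which chromatin regions opened or closed while PU.1 was restored. Macrophage and eosinophil genes stood at the gaining end and erythroid genes at the losing end. The 20 monocyte and macrophage genes held 9 gained and 2 lost regions among 59, led by the monocyte chemokine receptor Ccr2 (3 gained) and the myeloid receptor Cd300lf (2 gained). The 14 erythroid genes held 0 gained and 5 lost regions among 21, with 1 lost region each at Klf1, Epor, Nfe2, Ermap and Rhag, of which that of Epor had a later summit within 1 kb. Over all 68800 regions, including those with no gene within 100 kb, 3399 were gained, 3866 were lost and 21833 were open at all 4 times. Regions assigned to a gene held 3144 gained and 3547 lost.

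The gained total by itself was no larger than simulated lists with no change gave, which held 3405 gained and 2997 lost among the same 68800 regions. That simulation took its call chances from these same lists, so it does not settle how many calls no change would give. The totals also moved with the rule, to 1481 gained and 1956 lost at a score of at least 10. They were 9524 and 10825 with day 12 alone against day 0. In the data, 1997 regions were missing only at day 4, 348 only at day 8 and 3434 only at day 12, and 2173, 7630 and 2252 were open only at day 4, 8 and 12. With lists of equal length the 2838 gained regions exceeded the 1326, 1056 and 2101 regions missing only at day 4, 8 and 12, and the 4010 lost regions exceeded the 2547, 2218 and 3131 open only on those days. Gained and lost regions were less often near gene ends than constant regions. Only 8.41% (7.50 to 9.40) of gained and 12.9% (11.8 to 14.0) of lost regions were within 1 kb of a gene end, against 40.1% (39.4 to 40.7) of constant regions. Regions called in only 1 of the 2 day-12 libraries were also less often there, at 15.3% for CD11b-high only and 17.9% for total only against 34.1% for both, so a low share near gene ends also went with calls made in fewer lists. Regions inside genes and farther than 1 kb from the ends made up 49.6% (47.9 to 51.3) of gained, 43.3% (41.7 to 44.9) of lost and 32.3% (31.6 to 32.9) of constant regions.

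The gene with the most gained regions was Asap1, an Arf GTPase-activating protein on chromosome 15, with 7 gained and 1 lost among 38 regions. Itpr1, the inositol trisphosphate receptor, and Pmfbp1 each had 5 gained and 0 lost, and the ETS-family repressor Etv6, the CREB-family factor Creb5 and the translation initiation factor subunit Eif3h each had 5 gained and 1 lost. Among the 6 genes with 4 gained and 0 lost that the rule named were Syk, a tyrosine kinase of immune receptor signalling, the anti-apoptotic gene Bcl2, and the kinases Map3k9 and Stk10. The other 2, Zmiz1 and the thyroglobulin gene Tg, also had 4 gained and 0 lost, but at a score of at least 10 their gained minus lost numbers were -2 and -1. At the losing end, the phosphatase gene Ppm1h on chromosome 10 had 7 lost and 2 gained among 37 regions. Nav3 and the Hippo pathway factor Tead1 each had 5 lost and 0 gained, and Aff3 had 5 lost and 1 gained. Arhgap24, Rapgef2, Col26a1, the lymphoid repressor Bach2, the Rac exchange factor Prex1 and Slc44a3 each had 4 lost and 0 gained. Ranking by counts can favour genes with many regions, such as Zmiz1 with 33 and Creb5 with 32, although Map3k9 had 11 and Nav3 8. No count expected by chance was computed for single genes.

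**Figure D1:**
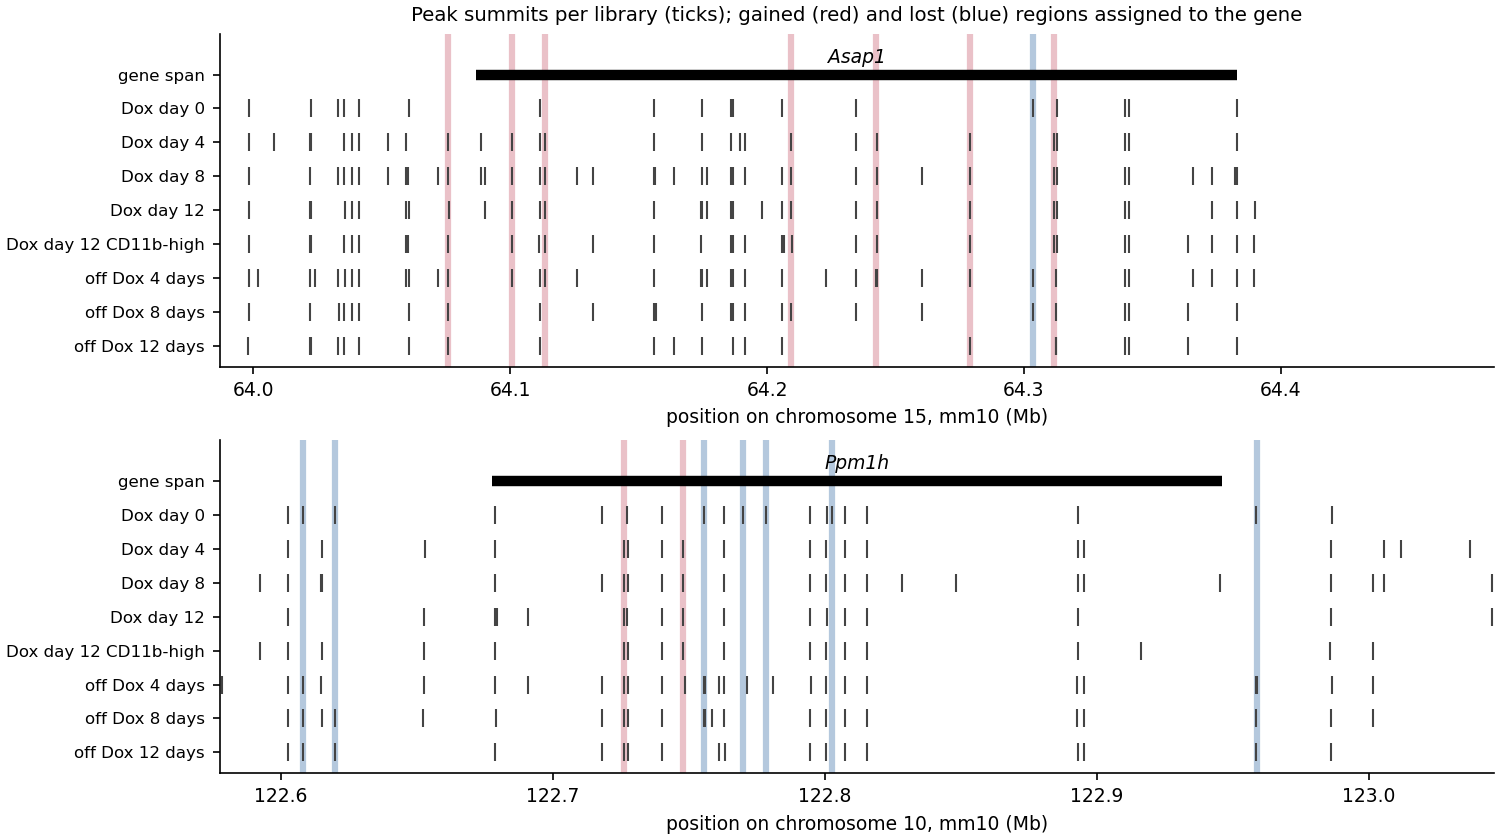
Summits (ticks) of each of the 8 libraries around Asap1 on chromosome 15 and Ppm1h on chromosome 10, by mm10 position in Mb, with gained regions in red, lost regions in blue and the gene span as a black bar. The 7 gained regions of Asap1 hold no summit at day 0, and the 7 lost regions of Ppm1h hold a day-0 summit and none at day 4, 8 or 12.

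Among the gained regions with the highest day-12 scores, the first lay on chromosome 10 at 43856403 to 43856749, outside genes and 17612 bp from Qrsl1. Its score was 43.3 at day 4, 50.4 at day 8 and 47.3 at day 12. Others lay inside Rufy3 (chromosome 5, 88630900 to 88631237), inside Antxr2 (chromosome 5, 98017871 to 98018497) and 212 bp from Higd1a (chromosome 9, 121857854 to 121858162). The Higd1a region had a day-0 summit 310 bp from its own, and the adjoining region at 121857488 to 121857848 ranked first among lost regions. All 5 lost regions with the highest day-0 scores, at Higd1a, Anapc5, Prr14, Gm34296 and a position on chromosome 14 with no gene within 100 kb, had a summit of a later restoration library at 336 to 395 bp. At such positions the called summit differed while accessible chromatin was called close by. After this was seen, regions with no summit of the other lists within 1 kb were counted, which left 3046 gained and 3178 lost. Gained regions were checked against the day-0 list alone and lost regions against those of day 4, 8 and 12. The filter was therefore stricter for lost regions, and it removed 353 gained and 688 lost. Asap1 then had 6 gained regions, Etv6 had 4, and Arhgap24, Rapgef2, Prex1 and Slc44a3 had 3 lost each. The strongest of the lost ones lay inside Esrrg (chromosome 1, 187946555 to 187946903), 15442 bp from Mreg (chromosome 1, 72227520 to 72227992), 286 bp from Gatd1 (chromosome 7, 141407699 to 141408098), 87324 bp from Prdm1 (chromosome 10, 44615593 to 44616171) and inside Bid (chromosome 6, 120911632 to 120912021). All 5 were open again at 4, 8 and 12 days off, and none was open in CD11b-high cells.

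Of the 18 gene lists, 3 stood apart from random lists with as many regions per gene. The monocyte and macrophage list was above 99.8% of random lists, with 5 genes gaining, 1 losing and 14 at 0 on balance. Besides Ccr2 and Cd300lf, Adgre1, which encodes the macrophage antigen F4/80, had 1 gained region, and the cathepsin gene Ctss had 1 lost. Its genes had 18 open regions at day 0, 31 at day 4, 32 at day 8 and 26 at day 12, and 37, 26 and 20 at 4, 8 and 12 days off. Per 10000 open regions of the library these were 5.08 (3.01 to 8.03) at day 0 and 7.62 (4.98 to 11.2) at day 12, with overlapping intervals. The 10 eosinophil genes, with 5 gained and 1 lost among 23 regions, were above 99.5% of random lists. There the lipoxygenase gene Alox15 had 3 gained regions, the eotaxin receptor gene Ccr3 and Siglecf had 1 each, and Ear1 had 1 lost. The Ccr3 count was -1 at a score of at least 10. Ccr3 (chromosome 9, 124017825 to 124031692) and Ccr2 (124101918 to 124109140) are neighbours, so the 2 lists share a locus. The erythroid list was above 0.225% of random lists, and above 9.76% when day 12 alone was set against day 0, a setting chosen after seeing the data. Per 10000 open regions, erythroid genes had 3.39 (1.75 to 5.92) at day 0 and 2.35 (1.01 to 4.62) at day 12. Eosinophil genes had 2.82 (1.35 to 5.19) and 4.40 (2.46 to 7.25), so these intervals overlapped as well. Epor, the erythropoietin receptor gene, had its lost region open again at 12 days off, but without regions that had a summit of the other lists within 1 kb it had 0 lost.

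The remaining lists did not stand apart. Oxidase and lysosome genes held 9 gained and 4 lost among 105 regions (percentile 94.7), with 2 gained each at Ctsd, Gpnmb and the lysosomal regulator Tfeb. Neutrophil and granulocyte genes held 8 gained and 5 lost among 63 (92.4), with 2 gained at the neutrophil collagenase gene Mmp8, 1 at the granulocytic factor Cebpe and 3 lost at the repressor Gfi1. Without regions that had a summit of the other lists within 1 kb, Gfi1 had 0 lost and Cebpe 0 gained, and this list reached the 98.6th percentile. That filter was stricter for lost than for gained regions. Myeloid transcription factors held 13 gained and 7 lost among 151 (91.9), with 2 gained each at Cebpb and Id2 and 1 at Cebpd, which had 0 without such regions. Stem and progenitor genes held 10 gained and 4 lost among 133 (91.7), with 3 gained at Cd34 and 2 at Lmo2, the latter 1 without such regions. Known PU.1 targets held 9 gained and 6 lost among 90 (84.4). Inflammatory and cytokine genes held 10 gained and 7 lost among 89 (85.6), with 2 gained each at Il1b and Ccl6 and 2 lost at Nfkbia, and reached the 99.4th percentile with lists of equal length. Dendritic cell genes held 5 gained and 2 lost among 76 (88.4), with 1 gained at Cd74, which had 0 without such regions, and megakaryocyte genes 5 gained and 2 lost among 58 (84.5), with 3 gained at the ETS factor Fli1, 2 without such regions.

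B cell genes held 0 gained and 3 lost among 21 (4.09), 1 each at Pax5, Ebf1 and Cd22, the last 0 without regions that had a summit of the other lists within 1 kb. T cell genes held 1 gained and 5 lost among 69 (9.63), and cell cycle genes 5 gained and 8 lost among 118 (22.1). Interferon response genes held 2 gained and 3 lost among 41 (36.1), 2 of the lost ones at Irf7, 1 without such regions. Mast cell and basophil genes held 1 gained and 2 lost among 52 (38.4), genes of non-blood tissues 1 and 2 among 25 (35.5), and housekeeping genes 4 and 5 among 57 (39.9). Over all 64638 regions assigned to a gene, 4.86% were gained and 5.49% lost.

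**Figure D2:**
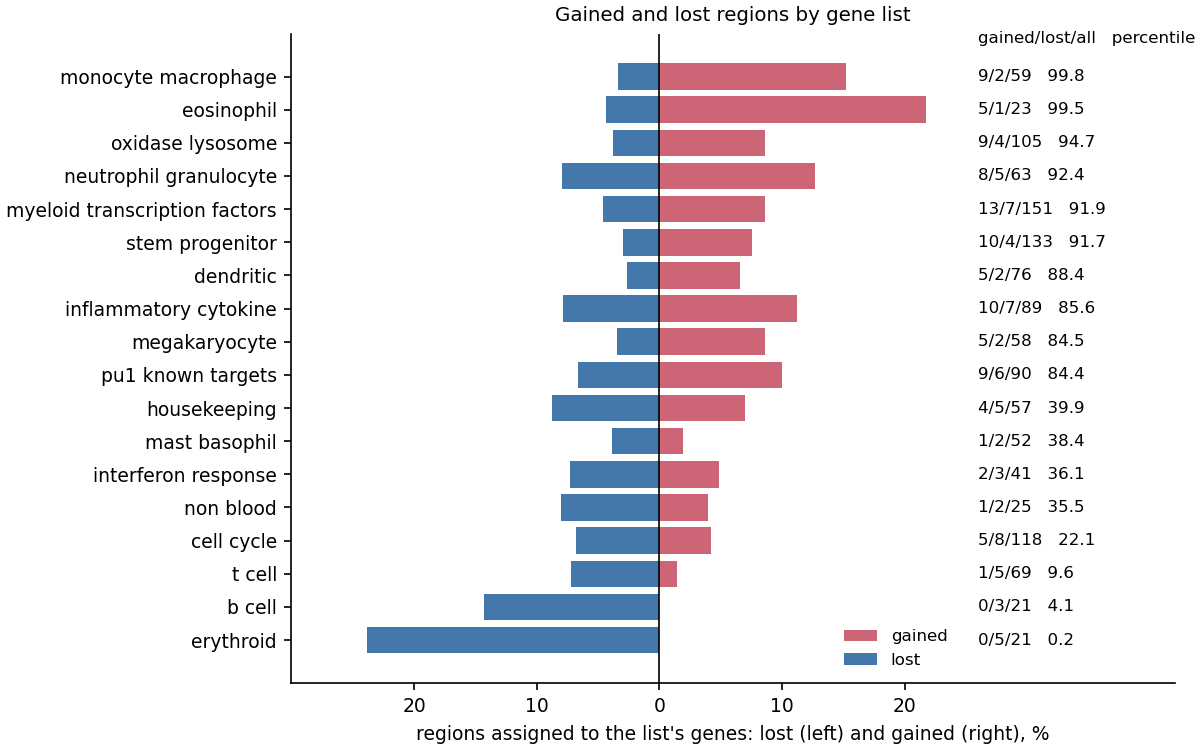
Share of the regions assigned to each of 18 gene lists that were gained (right, red) or lost (left, blue) during restoration, in percent, with the counts of gained, lost and all regions and the percentile among 10000 random lists at the right. The monocyte and macrophage list reads 9, 2, 59 and 99.8, and the erythroid list 0, 5 and 21, below all but 0.225% of random lists.

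The second comparison asked where each library lay between the start and the end of restoration. At 8 and 12 days after withdrawal the open regions lay on the day-0 side, and the libraries of day 8 and of CD11b-high cells on the day-12 side. Of 10825 regions open at day 0 and not at day 12, 42.7% (41.8 to 43.7) were open at 12 days off, against 18.7% (17.9 to 19.5) of 9524 regions open at day 12 and not at day 0. The day-0-only regions had 3.24 times the odds of being open (3.04 to 3.46). At 8 days off the shares were 64.0% (63.1 to 64.9) and 35.0% (34.1 to 36.0), an odds ratio of 3.30 (3.11 to 3.49). CD11b-high cells gave 0.241 (0.227 to 0.256), with 26.5% of day-0-only and 59.9% of day-12-only regions open, and day 8 gave 0.402 (0.379 to 0.427).

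The library at 4 days off held both kinds, with 69.5% of day-0-only and 57.6% of day-12-only regions open and an odds ratio of 1.67 (1.58 to 1.77). With lists of equal length this ratio was 1.11 (1.05 to 1.18), and at a score of at least 10 it was 1.31 (1.20 to 1.43). The fall from 1.67 to 1.11 shows that the lean towards day 0 at 4 days off depended on list length. The simulation without change, run only at full list lengths, gave 1.13 for the same library. Day 4 on Dox gave 1.22 (1.15 to 1.29), 1.42 (1.34 to 1.51) with lists of equal length and 1.77 (1.64 to 1.92) at a score of at least 10, beside 1.16 in that simulation. All 6 libraries were compared with the same day-0 and day-12 lists. The simulation, with odds ratios of 1.10 to 1.17, used full list lengths and its own call chances. It is no reference for lists of equal length or for a score limit. Leaving out any 1 chromosome kept the ratio at 12 days off between 3.19 and 3.29. By overlap of whole lists, the regions shared with day 0 made up 54.7% of those open in either library for day 12, 58.3% for 4 days off, 66.8% for 8 days off and 65.4% for 12 days off.

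**Figure D3:**
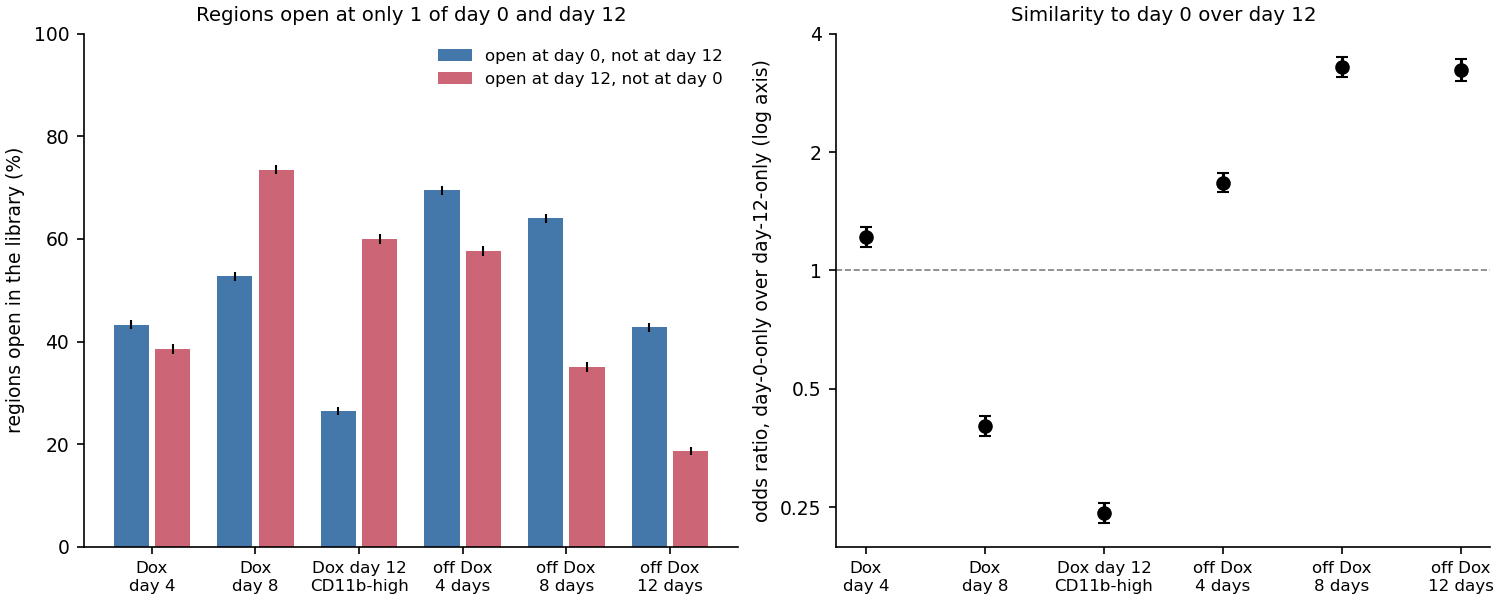
Left, percent of the 10825 regions open at day 0 but not day 12 (blue) and of the 9524 regions open at day 12 but not day 0 (red) that were open in each of 6 other libraries. Right, their odds ratio on a log axis, with 1 dashed; error bars are 95% counting intervals, and the values run from 0.241 in CD11b-high cells to 3.30 at 8 days off.

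The third comparison asked what became of gained and lost regions when PU.1 was knocked down again. Most gained regions were no longer called by 12 days off. Of the 3399, 74.8% (73.4 to 76.3) were open at 4 days off, 49.5% (47.8 to 51.2) at 8 and 26.2% (24.8 to 27.8) at 12. Of constant regions matched on day-12 score, 98.1%, 96.4% and 85.9% (84.7 to 87.1) were open at the same times. Of the lost regions, 48.4%, 44.8% (43.2 to 46.4) and 25.6% (24.2 to 27.0) were open at 4, 8 and 12 days off. With lists of equal length, 58.4%, 39.6% and 34.4% of gained regions were open at these times, so the steepness of their fall depended on list length.

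Regions missing from a single later restoration list behaved unlike gained regions. At 12 days off, 64.5% (62.4 to 66.6) of those missing only at day 4 and 62.3% (60.6 to 63.9) of those missing only at day 12 were open, while the simulation without change gave 62.5% for its gained regions. By pattern, 733 gained regions were closed at all 3 times off, 854 were open at 4 days only, 862 at 4 and 8 days and 726 at all 3 times. Of the regions open only at day 4, 8 or 12, 9.07% (7.89 to 10.4), 9.06% (8.42 to 9.72) and 10.1% (8.91 to 11.4) were open at 12 days off. These shares lay below the 25.6% of lost regions. At 8 days off they were 20.5%, 21.1% and 16.6%. At 4 days off they were 28.4%, 43.3% and 30.2%, beside 48.4% of lost regions. In the simulation without change, 33.9%, 29.4% and 21.9% of lost regions were open at 4, 8 and 12 days off, which leaves little distance to the 25.6% observed at 12 days. Of the lost regions, 609 were open at all 3 times off and 1386 at none. With lists of equal length the share of lost regions open at 4 days off was 28.5%, below the 38.1% at 12 days, so the order of the 3 times depended on list length.

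Genes whose gained regions closed again included Asap1 and Map3k9, with 4 gained regions each closed at both 8 and 12 days off, and Eif3h and Syk, with 3 each. At Sirpb1b, a signal-regulatory protein gene on chromosome 3, all 3 gained regions closed again, and at 8 and 12 days off 0 of its 4 regions were open. Bicd1 had 3 of 3 closed again. Gained regions that stayed open at all 3 times off numbered 2 each at Etv6, Zmiz1, Chn2, Ndst1, the coronin gene Coro2a and Cd34, the progenitor antigen gene. The 2 groups were not separate. Zmiz1, Chn2 and Coro2a also had 2 gained regions each closed at both 8 and 12 days off, and Asap1, Eif3h and Syk had 1 each that stayed open. Over all gained regions, 21.6% were closed at all 3 times off, 25.1% were open at 4 days only and 21.4% were open at all 3 times. Of the 7 lost regions of Ppm1h, 3 were open at 12 days off. Col26a1, Bach2, Slc44a3, Cubn and Ccdc162 had 2 lost regions each open at that time. Bach2 and Coro2a lie on chromosome 4, whose summit share and relative score rose at 8 and 12 days off, as given in the closing section. The effect of that rise on single genes was not tested.

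**Figure D4:**
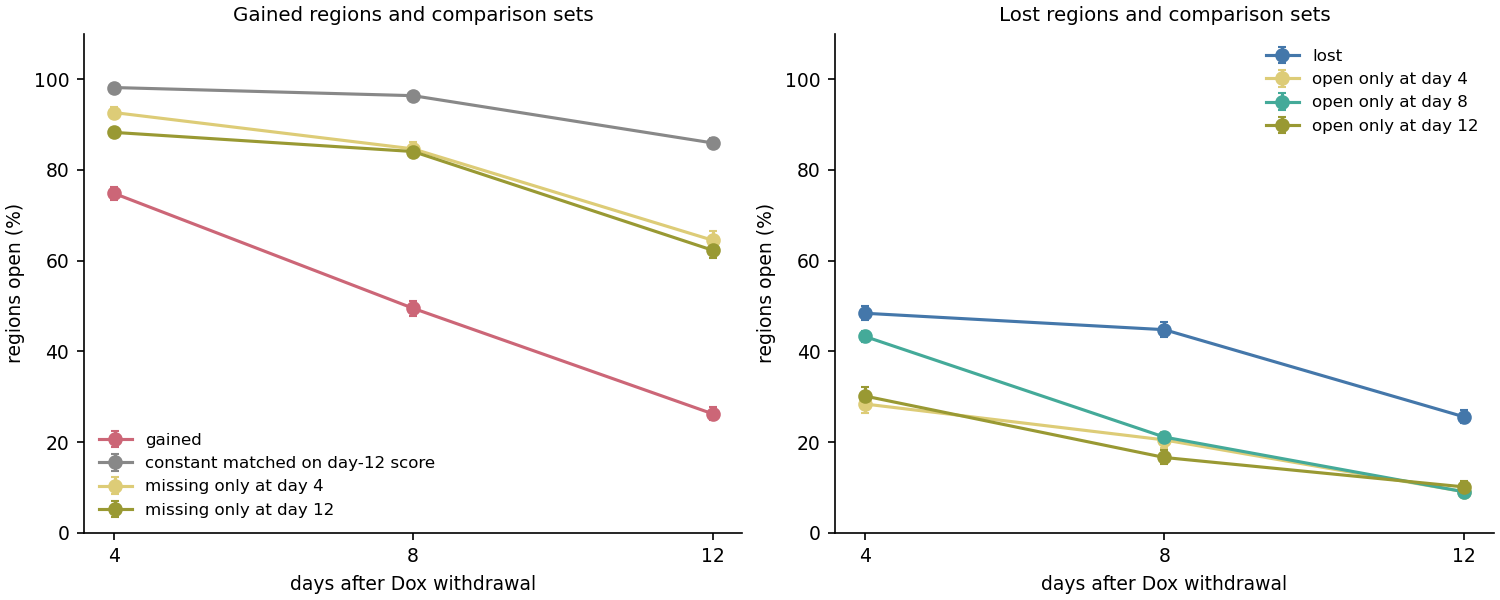
Percent of regions open at 4, 8 and 12 days after Dox withdrawal, with 95% counting intervals. Left, gained regions (red) reach 26.2% at 12 days beside 85.9% for constant regions matched on day-12 score. Regions missing only at day 4 and only at day 12 stand at 64.5% and 62.3%. Right, lost regions (blue) stand at 25.6% beside 9.06% to 10.1% for regions open only at day 4, 8 or 12. With lists of equal length, not drawn, gained regions stand at 34.4% and lost regions at 38.1% at 12 days.

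The fourth comparison asked how CD11b-high cells, sorted by a surface integrin of mature myeloid cells, differed from total viable cells of the same day. The 2 libraries shared 27777 regions, 67.0% of those open in either. By this ratio, which also depends on list length, day 0 and 8 days off were nearly as close, at 66.8%. CD11b-high cells had 7362 regions of their own and total cells 6332, and with lists of equal length these were 6136 and 6107. Of the 3399 gained regions, 84.0% (82.7 to 85.2) were open in CD11b-high cells, against 86.6% (85.4 to 87.7) of matched constant regions, and 7.45% (6.64 to 8.32) of lost regions were open there.

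Regions specific to either library were about equally frequent at day 0. That library held 39.7% (38.5 to 40.9) of the total-only and 39.0% (37.8 to 40.1) of the CD11b-high-only regions, an odds ratio of 1.03 (0.964 to 1.11), and at 12 days off the ratio was 1.09 (1.01 to 1.17). At a score of at least 10 the numbers of library-specific regions were 3001 and 2751. The genes with the largest excess of CD11b-high-only over total-only regions were Adamtsl1 with 6 and 0 total-only, and Cpne4, Ltbp1, the mitochondrial calcium uniporter gene Mcu and the 14-3-3 gene Ywhaz with 5 and 0. Total cells led at Srpk2 with 8 total-only and 2 CD11b-high-only regions, at the corepressor gene Bcor and at Lrba with 6 and 0, at Zfpm2 with 7 and 2 and at Ppp2r5c with 6 and 1. Itgam itself had 2 CD11b-high-only regions and 1 total-only region.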

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

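Settings without chromosome 4, with CD11b-high in place of total cells, without day 8, with gene lists from day 12 alone, with the nearest gene end and with no summit of the other lists within 1 kb were chosen after seeing the data. Over the settings run, the odds ratios ran from 2.69 to 3.65 at 8 and 12 days off and from 0.173 to 0.485 at day 8 and in CD11b-high cells. At day 4 they ran from 1.08 to 1.77 and at 4 days off from 1.11 to 1.72. The lower ends lay near or within the 1.10 to 1.17 simulated without change. That simulation was run at full list lengths only and is no reference for the other settings. Leaving out chromosome 4 moved none of the 12 values recomputed beyond its interval. No paired analysis was possible because each group held 1 library. The planned motif settings were not run, since no genome sequence was used here. List length limits these results, beside the 1 library per group: a region missed in a shallower list counts as not open. The read depth that would separate missed from closed regions is not given in the sources used here. The cause of the shifts below was not tested, except where a setting by its construction keeps fewer or more regions.

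With a score of at least 10, fewer summits remained: 1481 regions were gained, 1956 lost, 3001 open only in CD11b-high cells and 2751 only in total cells at day 12. Odds ratios were then 1.77 at day 4, 0.296 at day 8, 0.173 in CD11b-high cells, 1.31 at 4 days off and 3.55 at 12 days off. Gained regions were open at 80.1%, 53.3% and 19.7% at 4, 8 and 12 days off, and lost regions at 50.9%, 46.4% and 19.8%. With lists of equal length the ratios were 1.42 at day 4, 0.342 at day 8 and 1.11 at 4 days off, gained regions were open at 58.4%, 39.6% and 34.4%, lost regions at 28.5%, 38.9% and 38.1%, and inflammatory and cytokine genes stood apart at the 99.4th percentile.

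With summits extended by 250 bp the ratios were 1.08 at day 4, 0.311 at day 8, 0.220 in CD11b-high cells, 1.52 at 4 days off and 3.65 at 12 days off. Gained regions were open at 24.7% at 12 days off and lost regions at 50.9% and 47.3% at 4 and 8 days. With 75 bp the ratios were 0.485 at day 8, 0.291 in CD11b-high cells, 1.49, 2.83 and 2.69 at 4, 8 and 12 days off, gained regions were open at 30.1% at 12 days, and lost regions at 40.6%, 38.5% and 23.3%.

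Requiring only day 8 and 12 gave 6999 gained regions, leaving out day 8 gave 6138 lost regions, and day 12 alone gave 9524 gained and 10825 lost regions, with the erythroid list at the 9.76th percentile. Without regions that had a summit of the other lists within 1 kb, gained regions were open at 23.9% at 12 days off, lost regions at 50.3% and 46.9% at 4 and 8 days, and the neutrophil and granulocyte list reached the 98.6th percentile. The monocyte and macrophage and eosinophil lists stood apart in all 5 other settings run for lists. List percentiles were not computed with a score of at least 10, with other summit extensions or with only day 8 and 12 required. Whether these lists stand apart under those planned settings was therefore not tested.

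Over 808 comparisons of 101 named genes in 8 settings, the gained minus lost number changed by no more than the square root of the gene's gained and lost regions in 709, by more in 73 and took the other sign in 26, which fell on 19 genes. Among these, with a score of at least 10 it became 2 at Srgn, 1 at Ywhaz, Gfi1b, Fosl2, Cdkn1a and Selp, -1 at Tg, Ltbp1, Fcgr1, Ccr3, Itgax and Tcf4, -2 at Zmiz1 and -3 at Bcor. Those with lists of equal length included 2 at Cdk6, 1 at Fosl2, and -1 at Bcor, Itgb2, Cd200r3 and Tcf4. With day 12 alone it became 3 at Zfpm2, -1 at Itgb2 and Cd200r3, -2 at Ltbp1 and -3 at Bcor.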

Other observations

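Some tests were chosen only after the results they bear on were seen. These were the tests of the share near gene ends, of later libraries against day 0 and 4 and of day 0 on chromosome 4. The odds ratio without chromosome 4 and the restriction to regions with no summit of the other lists within 1 kb were also chosen then.

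For 3 genes of the lists, picked after their values were seen, the number of open regions is given per library, as values only, since these counts also move with list length. At Il1b, which encodes the cytokine interleukin-1 beta, 0 regions were open at day 0, then 3, 4 and 3 at day 4, 8 and 12, and 2, 2 and 0 at 4, 8 and 12 days off. Cd74, the invariant chain of antigen presentation, had 1, 2, 3 and 3, and then 1, 1 and 1 at the same times. Pax5, the B cell factor, had 4, 3, 1 and 1 open regions at day 0, 4, 8 and 12, 0 in CD11b-high cells, and 1, 2 and 3 off Dox. The longest lists were those of day 8 and 4 days off, with 47060 and 51175 summits, and the shortest that of 12 days off, with 31957. Each of these counts comes from 1 library and carries no replicate error.

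At 8 and 12 days off the libraries lay on the day-0 side, with odds ratios of 3.30 (3.11 to 3.49) and 3.24 (3.04 to 3.46). At 12 days off the ratio was 3.23 with equal lists, 3.55 with a score of at least 10 and 3.23 without chromosome 4. These values argue against unequal list length, weak summits and chromosome 4, in that order, as the whole cause. The score limit kept unequal parts of the lists, since median scores were 9.40 at day 12, 10.1 at 12 days off and 11.5 at day 0. Missed detection at day 0 as the whole cause of gained regions is argued against by the 64.5% of regions missing only at day 4 that were open at 12 days off, against 26.2% of gained regions, and chance summits at day 0 by the 10.1% of regions open only at day 12, against 25.6% of lost regions. Chance calls still make up an unknown part of both sets, and the simulation without change gave 21.9% for lost regions. The ratios are consistent with a partial return to the starting chromatin state, a hypothesis that rests on 1 library per time and leaves time in culture and library batch untested.

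Chromosome 4 carried 6.26% to 6.62% of summits in the 5 libraries up to day 12, 6.70% at 4 days off, 7.31% (7.07 to 7.57) at 8 and 7.46% (7.18 to 7.76) at 12 days off. Over regions open in all 8 libraries, its score relative to the other chromosomes was higher by 0.16 (0.14 to 0.18) on the log2 scale at 8 and 12 days off than over the 4 restoration libraries, the largest upward shift of any chromosome in this comparison, and 100% of its 16 windows of 10 Mb were higher, against 98 of 246 windows elsewhere. A signal following the share of regions near gene ends is argued against by the 11 chromosomes where that share was larger. Their median change was -0.0345 (log2). That share was taken over regions open in all 8 libraries and is not gene density, which was not tested. Low PU.1 itself is argued against by the relative score of 1.02 at day 0, below 1.17 and 1.19 at 8 and 12 days off. A copy number gain of chromosome 4 in part of the cells, spreading after withdrawal, is a candidate explanation that these values fit, while read depth along chromosomes was not analysed here. Other chromosome-wide shifts occurred, with X at -0.15 in the same comparison and chromosome 11 at -0.23 (-0.26 to -0.20) in the other 6 libraries against day 0 and 4, so a shift of library origin stays open for chromosome 4 too.

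Regions that opened during restoration differed in how often they closed again, after matching on day-12 score. Regions open at day 8 and 12 but not at day 0 or 4, which are not among the gained regions, were open at 12 days off in 18.0% (16.5 to 19.6), against 23.9% (22.3 to 25.6) of gained regions, open from day 4, which may reflect the order of opening, but the second set had to be found in 1 more list, and stronger detection stays open. Of gained regions near a gene end 40.2% (34.5 to 46.1) were open, against 21.7% (17.0 to 26.9) elsewhere, yet among regions with no day-0 summit within 1 kb the shares were 28.0% (21.2 to 35.7) of 157 and 22.3% (16.0 to 29.6), a difference not detectable at this number. A summit that moved within a wide accessible stretch could therefore account for much of the gene-end difference, and the 2 cannot be told apart with 157 regions. Gained regions not open in CD11b-high cells were open at 12 days off in 22.1% (18.7 to 25.8) against 23.2% (19.7 to 27.0) of those open there, and overlapping intervals, set beforehand as evidence against a difference, only bound it, so this stays open.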
